A study of Mus musculus with 8 samples.

How the data were processed

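Total RNA was measured in the aorta of newborn (p0) Lox KO and WT mice on an albino C57BL/6J background. Per the labels, each of the 8 arrays held 1 pool of 8 pups of like genotype, with 2 arrays for each of the 4 groups of genotype and segment. The labels place the ascending segment between the aortic valve and the ductus arteriosus, and the descending segment between the vena cava and the diaphragm. RNA was amplified and biotin labelled with NuGEN kits (Ovation Pico WTA and Encore Biotin) and hybridized to Affymetrix mouse gene arrays, as the protocol notes state. The deposited values are on the log2 scale and were made by the authors with RMA in Affymetrix Expression Console, whose versions and options are not given in the sources used here. The scale was checked on the values themselves. Array medians over all probe sets lay between 5.11 and 5.19, and no column of values was left unused.

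The table held 41345 probe sets. Of these 23525 had exactly 1 gene symbol in the platform table, 1810 had several and 16010 had none. The single-symbol probe sets covered 22184 genes, 1082 of them with more than 1 probe set, and the probe set with the highest mean over the 8 arrays was used for each gene. Genes with a mean below the 25th percentile, at 4.11 log2, were left out as dim, which left 16638. Loxl2 and other genes measured only by probe sets shared between genes were not used in the comparisons.

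Each gene was fitted in limma 3.58.1 (R 4.3.3) with 1 coefficient per group over all 8 arrays and no covariate. Spread was moderated by eBayes with default settings (residual df 4, prior df 4.51), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. Genes at an adjusted p under 0.05 are said to rise, fall or change. Comparisons were KO against WT in each segment, ascending against descending in each genotype, the genotype by segment interaction, and both factors averaged over the other. The p-values measure spread between pools, not between pups, and RNA levels are relative to the total RNA of each pool. Replicate numbers were not taken as pairs, since the labels do not tie them to a litter or a day.

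The analysis also used 44 gene lists, written from general knowledge before the data were examined, as were the comparisons, tests and alternatives. They covered matrix, muscle and signalling genes, stress and metabolic programmes, and markers of cell types and neighbouring tissues. Of 1097 members written, 1014 matched a gene and 982 were tested. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run on the same lists. Preset camera called 16, 19, 18 and 14 lists in the 4 comparisons in the order given, fry called 12, 9, 7 and 4, and camera with an estimated correlation called 0 in each. Counts within a list are given with the adjustment over all genes and over the list alone. Further marker lists, of platelets, neutrophils and lung secretory genes, were written after the data had been seen.

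The genes named were fixed by a rule. It took the lysyl oxidase family, the 10 largest rises and falls among called genes whose arrays did not overlap, up to 4 members of each list by smallest p with at least 1 that did not pass where any did not, and up to 10 genes called in the interaction. Predicted genes, clone names, microRNAs, small nucleolar RNAs and olfactory and vomeronasal receptors were skipped among the largest changes. Such names made up 28, 18, 7 and 10 of the genes called in the 4 comparisons, in the order given. Genes named outside the rule are marked as chosen after their values were seen.

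Alternatives were no filter on dim genes, a filter at the 50th percentile, a trended robust prior, cyclic loess between arrays, arrays shifted to 1 median, array weights, the replicate number as a block, the mean of a gene's probe sets, and all probe sets tested separately. Others were a test against 1.2-fold, a minimum of 1.5-fold, a fit on only the arrays compared, and each array left out in turn with the spread pooled over the groups. Where an array was left out, the lone array of its group was assumed to vary like the other groups. The method was tested on simulated data for KO against WT ascending, with 200 genes changed in each of 5 draws. It called 9.85% of genes changed by 0.5 log2, 85.4% by 1 and 99.7% by 2, with 4% of calls false. A list shifted by 0.3 log2 was called in 5 of 5 draws by preset camera and in 1 of 5 with an estimated correlation. No other list was called, but correlation between genes was not simulated. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.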

Results

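RNA levels were measured on Affymetrix gene arrays in the aorta of newborn mice lacking Lox (KO) and of wild-type (WT) mice. Lox encodes lysyl oxidase, the enzyme that starts the crosslinking of elastin and collagen fibres. The aorta was taken as an ascending segment, reaching from the valve to the ductus arteriosus, and a descending segment that ended at the diaphragm. Each of the 4 groups of genotype and segment had 2 arrays, and each array measured a pool of 8 pups, so n = 2 pools per group in every value given. The number of arrays limits the precision. Across genes, which are not independent replicates, the arrays of a group had Pearson correlations of 0.988 to 0.992. The first principal component held 34.2% of the variance and separated KO from WT arrays, and the second held 27.2% and separated ascending from descending arrays.

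Lox itself was lower in KO pools in both segments. It fell by 2.73 (SE 0.11, adjusted p = 5.34e-05) on the log2 scale in the ascending aorta and by 2.80 (SE 0.11, adjusted p = 4.42e-05) in the descending aorta, a 6.65-fold and a 6.94-fold difference. The KO arrays kept a Lox signal of 8.51 to 8.87, against 11.24 to 11.60 on the WT arrays, and where the probes lie relative to the deleted part is not given in the sources used here. The related crosslinking enzymes did not pass the test. Loxl1 differed by 0.02 (adjusted p = 0.949) in ascending and 0.32 (adjusted p = 0.196) in descending aorta, Loxl3 by 0.35 (adjusted p = 0.1) and 0.47 (adjusted p = 0.0505), and Loxl4 by -0.06 (adjusted p = 0.797) and 0.19 (adjusted p = 0.343). Loxl2 was not analysed here. Lox differed by 0.21 (adjusted p = 0.499) between the WT segments.

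**Figure D1:**
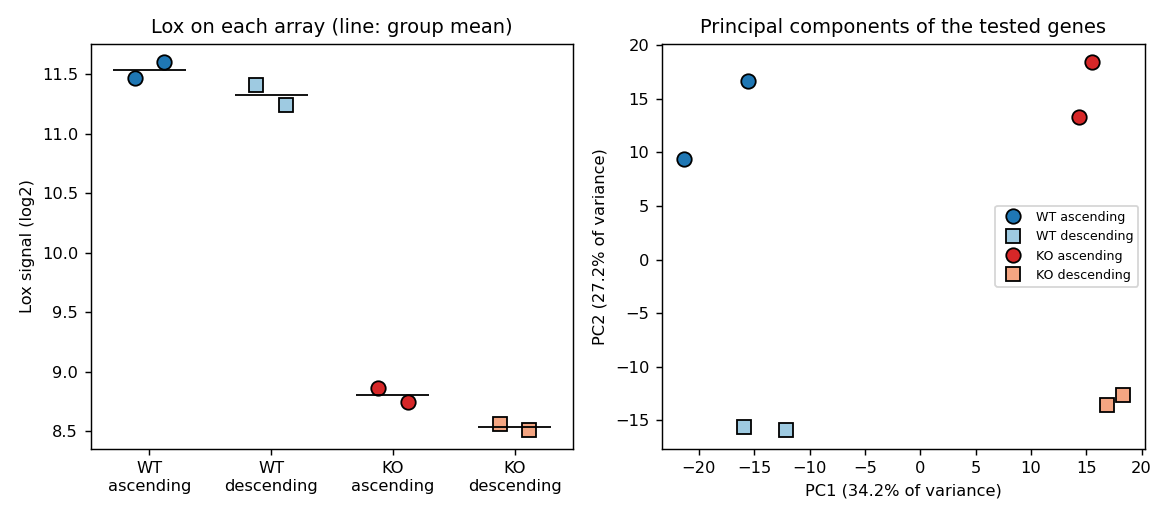
Left, Lox signal in log2 units on each of the 8 arrays with a line at each group mean, from 8.51 to 8.87 on KO arrays and 11.24 to 11.60 on WT arrays. Right, the 8 arrays on the first and second principal components of the tested genes, with genotypes apart on the first and segments apart on the second.

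The first comparison asked which genes differ without lysyl oxidase in the ascending aorta. Col8a1, a short-chain collagen of vessel walls, rose by 3.41 (SE 0.22, adjusted p = 0.000551) on the log2 scale, and Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 2.95 (SE 0.18, adjusted p = 0.000551). Csta3, an inhibitor of cysteine proteases of the stefin A family, rose by 3.76 (SE 0.34, adjusted p = 0.00374). Ccl7 and Ccl2, chemokines that attract monocytes, rose by 2.20 and 2.07. The largest called falls after Lox were in Galnt15, a glycosyltransferase, by 1.80 (SE 0.38, adjusted p = 0.0477), and in Angptl4, an inhibitor of lipoprotein lipase, by 1.75 (SE 0.27, adjusted p = 0.0183). Trpm3, a cation channel, fell by 1.51 (SE 0.14, adjusted p = 0.00374). Other large rises were in Cstdc4 (3.41), S100a8 (2.56), Stfa3 (2.43), Stfa2l1 (2.35) and Retnlg (2.19). Falls were also called in Tecrl (-1.73), Car3 (-1.65), Fam107a (-1.62), Il31ra (-1.42), Trp53inp1 (-1.41) and Kcnn2 (-1.34). Csta3, Cstdc4, Stfa3 and Stfa2l1 are close in sequence, and their signals were not separated further.

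Genes of the extracellular matrix changed in the ascending KO aorta. Among enzymes that process collagen, 5 of 22 tested members rose, 0 fell and 17 did not pass (9 rose and 0 fell when adjusted over the list alone), with P4ha1 (1.01), a prolyl hydroxylase, Plod2 (0.66), a lysyl hydroxylase, and the transglutaminase Tgm2 (0.83) higher. That list had a median of 0.21 log2 with an adjusted p of 0.000341 by camera, and adjusted p = 0.454 with an estimated correlation. Of the fibrillar collagens, Col11a1 rose by 1.80 (SE 0.11, adjusted p = 0.000551), while Col1a1 differed by 0.26 (adjusted p = 0.222). The fibrillar list had a median of 0.19 log2 with an adjusted p of 0.0014 by camera, and adjusted p = 0.454 with an estimated correlation, with 1 of 11 members higher over all genes and 2 adjusted over the list alone. Its median was 0.13 without WT ascending replicate 1 and 0.09 without KO ascending replicate 1. Matricellular proteins, which bind matrix and cells, went both ways, and 5 of 33 rose and 5 fell over all genes, and 10 rose and 7 fell adjusted over the list alone. Among them Ccn5 rose by 1.85 and Thbs1, thrombospondin 1, by 1.57, and Ecm2 fell by 0.76 (camera adjusted p = 0.677).

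Of the elastic fibre components only Ltbp2, which binds fibrillin, passed over all genes, with a rise of 0.52 (SE 0.10, adjusted p = 0.0312). Eln, elastin itself, differed by 0.26 (adjusted p = 0.249). That list had a median of 0.05 log2 (camera adjusted p = 0.455), and 1 member passed adjusted over the list alone. Among matrix proteases and inhibitors, 4 of 48 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. The metalloproteases Adamts8 (1.18) and Mmp8 (1.99) rose and the inhibitor Timp4 (-1.05) fell. Neutrophil markers rose too, and a neutrophil source of Mmp8 was not tested. The proteoglycan Fmod, fibromodulin, rose by 0.96, and Vcan, versican, fell by 0.53. The integrin and focal adhesion list rose, with Itga11, a collagen receptor subunit, at 1.37, Itga4 at 0.84 and Itgb3 at 0.61. It had 3 of 30 members higher and 0 lower, the same 3 adjusted over the list alone, and a median of 0.06 log2 with an adjusted p of 0.0253 by camera, and adjusted p = 0.592 with an estimated correlation. Its call ended without WT ascending replicate 1 (adjusted p = 0.0605, median 0.04) and without KO ascending replicate 2 (adjusted p = 0.253). Its median was 0.13 without WT ascending replicate 2 and 0.16 without KO ascending replicate 1.

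Genes of smooth muscle contraction showed no shift as a list in the ascending aorta, with a median of 0.03 log2 (camera adjusted p = 0.692). Mustn1 fell by 0.92 (SE 0.13, adjusted p = 0.0164), 23 of 24 members did not pass, and 2 were lower adjusted over the list alone. Myocd, the coactivator that drives contractile genes, differed by -0.43 (adjusted p = 0.0727). The TGF-beta list likewise had a median of 0.01 (camera adjusted p = 0.817), with Inhba higher by 0.72 and Tgfbr3 lower (-0.64). Adjusted over the list alone, 7 of its 34 members were higher and 4 lower.

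Stress and metabolic groups rose in the ascending KO aorta. Among immediate early genes, transcription factors and regulators induced within minutes of a stimulus, 9 of 23 tested members rose, 0 fell and 14 did not pass (16 rose and 0 fell when adjusted over the list alone). Egr1 (1.85), Ier3 (1.37) and Egr2 (1.15) were examples, and the list had a median of 0.79 log2 with an adjusted p of 3.72e-12 by camera, and adjusted p = 0.306 with an estimated correlation. In sterol and fatty acid synthesis 9 of 18 tested members rose, 0 fell and 9 did not pass (12 rose and 0 fell when adjusted over the list alone), among them the sterol pathway genes Cyp51 (1.26), Hmgcs1 (1.12) and Insig1 (0.92). The list had a median of 0.57 log2 with an adjusted p of 3.68e-10 by camera, and adjusted p = 0.36 with an estimated correlation. For hypoxia and glycolysis 4 of 27 rose and 0 fell over all genes, and 13 rose and 0 fell adjusted over the list alone, including the glucose transporter Slc2a1 (0.78) and the lactate transporter Slc16a3 (0.95). The median was 0.32 log2 with an adjusted p of 5.62e-07 by camera, and adjusted p = 0.164 with an estimated correlation.

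In the unfolded protein and amino acid stress list 2 of 28 rose and 1 fell over all genes, and 10 rose and 1 fell adjusted over the list alone, with the chaperones Hyou1 (0.77) and Calr (0.59) higher and Vldlr lower (-0.86). Its median was 0.21 log2 with an adjusted p of 9.25e-05 by camera, and adjusted p = 0.179 with an estimated correlation. Heat shock genes included Hspa1a (0.89), whose paralog Hspa1b is nearly identical, and Hsph1 (0.58). In that list 2 of 12 rose and 0 fell over all genes, and 4 rose and 0 fell adjusted over the list alone, and the median was 0.26 log2 with an adjusted p of 0.00183 by camera, and adjusted p = 0.454 with an estimated correlation. Oxidative phosphorylation had a median of -0.07 log2 with an adjusted p of 0.0293 by camera, and adjusted p = 0.592 with an estimated correlation, and none of its 34 members passed, over all genes or adjusted over the list alone (0 in each). That call ended without WT ascending replicate 2 (adjusted p = 0.117), without KO ascending replicate 1 (0.0998), with the filter at the 50th percentile (0.0791) and with cyclic loess scaling (0.0703).

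Inflammatory groups rose together in the ascending KO aorta, beside markers of blood cells. In the cytokine and chemokine list 9 of 27 tested members rose, 0 fell and 18 did not pass (14 rose and 0 fell when adjusted over the list alone), with the neutrophil attractants Cxcl1 (1.56) and Cxcl2 (1.26) and the chemokine Ccl8 (1.00). Its median was 0.56 log2 with an adjusted p of 1.01e-08 by camera, and adjusted p = 0.306 with an estimated correlation, and 0.36 without KO ascending replicate 2. Among interferon response genes 4 of 17 rose and 0 fell over all genes, and 7 rose and 0 fell adjusted over the list alone, including Isg15 (1.44) and Rsad2 (1.03). The median was 0.41 log2 with an adjusted p of 2.66e-08 by camera, and adjusted p = 0.454 with an estimated correlation. For macrophages and myeloid cells 4 of 25 rose and 0 fell over all genes, and 12 rose and 0 fell adjusted over the list alone, led by S100a8 (2.56) and S100a9 (2.04), proteins abundant in neutrophils, and Cd14 (1.18). The median was 0.38 log2 with an adjusted p of 6.87e-07 by camera, and adjusted p = 0.306 with an estimated correlation. On the same arrays 12 of 18 neutrophil markers, listed after the data had been seen and 8 of the 18 also in the fixed lists, were higher, with a median of 1.60. Of platelet markers, also listed afterwards, 6 of 9 were higher, with a median of 0.88.

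Markers of other cell types also differed. In the erythroid list 1 of 12 rose and 0 fell over all genes, and 4 rose and 0 fell adjusted over the list alone, with Tspo2 at 1.24 and a median of 0.43 log2 with an adjusted p of 0.000341 by camera, and adjusted p = 0.454 with an estimated correlation, or 0.28 without KO ascending replicate 2. Endothelial genes fell as a list, and 0 of 24 rose and 2 fell over all genes, and 1 rose and 9 fell adjusted over the list alone, including Kdr, a receptor for vascular endothelial growth factor (-0.62), and Nos3, the endothelial nitric oxide synthase (-0.65). The median was -0.21 log2 with an adjusted p of 0.000341 by camera, and adjusted p = 0.454 with an estimated correlation, and -0.12 without WT ascending replicate 2. For brown and white fat 0 of 22 rose and 5 fell over all genes, and 0 rose and 7 fell adjusted over the list alone, among them Adipoq, adiponectin (-1.29), and Car3 (-1.65). The median was -0.43 log2 with an adjusted p of 0.000341 by camera, and adjusted p = 0.592 with an estimated correlation. That median was -0.74 without WT ascending replicate 1, and the call ended without WT ascending replicate 2 (adjusted p = 0.111, median -0.14).

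Among fibroblast and adventitia genes Meox1 rose by 0.66, Dpt and Pdgfra were lower (-0.55 and -0.60), and 1 rose and 4 fell adjusted over the list alone. The list had a median of -0.12 log2 with an adjusted p of 0.0322 by camera, and adjusted p = 0.576 with an estimated correlation. It lost its call without WT ascending replicate 1 (adjusted p = 0.106), without KO ascending replicate 1 (0.165), with the filter at the 50th percentile (0.0791) and with cyclic loess scaling (0.0547). Its median was -0.19 without WT ascending replicate 2 and -0.18 without KO ascending replicate 2. Genes of lymphocytes and thymus did not pass (median -0.25, camera adjusted p = 0.229); the thymocyte gene Cd3d read 7.71 on WT ascending replicate 1 and 5.78 on replicate 2.

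In the ascending aorta limma called 455 of 16638 genes between KO and WT at an adjusted p under 0.05, 257 higher and 198 lower, and 371 of them differed by at least 1.5-fold. The groups' arrays did not overlap in any of the 455, which the test itself favours, nor in 49.5% of tested genes (33.3% by chance). Of 79 named genes called, 10 kept the call under every alternative that tested them, namely Lox, Csta3, Col8a1, Ptgs2, Trpm3, Col11a1, P4ha1, Adamts8, Itga11 and Ier3. The count was 105 and 64 without WT ascending replicates 1 and 2, 90 and 143 without KO ascending replicates 1 and 2, and 241 without either WT descending array. It was 100 when only the arrays compared entered the fit, 65 in a test against 1.2-fold, 303 without the filter on dim genes, 756 with a filter at the 50th percentile, 1014 with a trended robust prior and 39 when all probe sets were tested.

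The second comparison asked the same question in the descending aorta. Col8a1 rose by 2.57 (SE 0.22, adjusted p = 0.00407) on the log2 scale and Ccn5, a matricellular protein, by 2.12 (SE 0.20, adjusted p = 0.00423). Igfbp2, which binds insulin-like growth factors, rose by 1.83 (SE 0.19, adjusted p = 0.00564). Timp4, an inhibitor of matrix metalloproteases, fell by 1.48 (SE 0.12, adjusted p = 0.00407), Npy1r, a neuropeptide Y receptor, by 1.59 (SE 0.18, adjusted p = 0.00893) and Cd36, a fatty acid transporter, by 1.37 (SE 0.23, adjusted p = 0.0309). The largest rises also took in plasma proteins made by the liver, namely Fgg (2.82), Serpina1d (2.81), Afp (2.61), Fgb (2.54), Alb (2.22), Ahsg (2.06) and Ambp (1.98). The largest fall was in Sftpc, a lung surfactant protein (-4.35). Further falls were called in Arap2 (-1.29), Art3 (-1.22), Hapln1 (-1.17), Rbp7 (-1.15) and Pi15 (-1.13). Fgg was 1.84 without KO descending replicate 2.

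Matrix genes changed in the descending aorta as well. In collagen processing 3 of 22 rose and 0 fell over all genes, and 5 rose and 1 fell adjusted over the list alone, including P4ha1 (1.06), Plod2 (0.96) and P4ha3 (0.57). The median was 0.19 log2 with an adjusted p of 0.00354 by camera, and adjusted p = 0.519 with an estimated correlation. Elastic fibre components rose as a list, with Fbn2, a fibrillin (0.64), and Ltbp2 (0.63) as its 2 called members of 20, and as many adjusted over the list alone. Its median was 0.12 log2 with an adjusted p of 0.00457 by camera, and adjusted p = 0.329 with an estimated correlation. Integrins included Itga11 (1.52), Itga4 (1.42) and Itgb3 (0.55), and 3 of 30 rose and 0 fell over all genes, and 3 rose and 0 fell adjusted over the list alone. The median was 0.11 log2 with an adjusted p of 0.0137 by camera, and adjusted p = 0.519 with an estimated correlation. Without KO descending replicate 1 the integrin median was -0.01 and its call ended (adjusted p = 0.11).

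Of the fibrillar collagens, 1 of 11 passed over all genes and 1 adjusted over the list alone. It was Col11a1, which rose by 1.22 (SE 0.11, adjusted p = 0.00423), while Col1a1 differed by 0.15 (adjusted p = 0.499). The camera test of the list gave an adjusted p of 0.0959. The proteoglycans Fmod (1.01) and Prelp (0.92) rose. Adamts8 (1.45) and Adamts12 (0.61) rose among the matrix proteases, and Thbs1 (1.12) rose and Ecm2 (-0.79) fell among matricellular proteins. The smooth muscle contractile list had a median of -0.0016 (camera adjusted p = 0.764), with Mustn1 lower (-0.78), and 1 member higher and 1 lower adjusted over the list alone. In the TGF-beta list 4 of 34 rose and 1 fell over all genes, and 9 rose and 2 fell adjusted over the list alone, including Smad6 (0.77), Pmepa1 (0.59) and Ccn2 (0.67), at a median of 0.05 (camera adjusted p = 0.102). A second probe set of Ccn2 had the other sign.

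The sterol and fatty acid synthesis list rose in the descending aorta too. In it 10 of 18 tested members rose, 0 fell and 8 did not pass (15 rose and 0 fell when adjusted over the list alone), with Cyp51 (1.24), Hmgcs1 (1.23) and Insig1 (1.02). The median was 0.67 log2 with an adjusted p of 1.96e-14 by camera, and adjusted p = 0.305 with an estimated correlation. Cell cycle genes rose, and 4 of 33 rose and 0 fell over all genes, and 8 rose and 0 fell adjusted over the list alone, among them Mcm5 (1.28), Mcm2 (1.17) and Mcm3 (0.91), parts of the helicase of DNA replication. The median was 0.27 log2 with an adjusted p of 5.41e-08 by camera, and adjusted p = 0.519 with an estimated correlation. For hypoxia and glycolysis 2 of 27 rose and 0 fell over all genes, and 10 rose and 0 fell adjusted over the list alone, with Pfkl, a phosphofructokinase (0.62). The median was 0.28 log2 with an adjusted p of 9.85e-07 by camera, and adjusted p = 0.175 with an estimated correlation. In the unfolded protein and amino acid stress list 3 of 28 rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone, including Hyou1 (0.78) and Shmt2 (0.70) upwards. The median was 0.23 log2 with an adjusted p of 0.000195 by camera, and adjusted p = 0.22 with an estimated correlation. Oxidative phosphorylation fell as a list (median -0.20, adjusted p = 1.56e-06; adjusted p = 0.329 with an estimated correlation), although 0 of 34 members passed over all genes and 0 adjusted over the list alone. The fat list, with genes of brown fat, a tissue rich in mitochondria, was lower on the same arrays (means 7.12 and 7.45 log2 against 7.87 and 7.66 on WT).

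Immediate early and inflammatory lists rose in the descending KO aorta with few called members. For immediate early genes 2 of 23 rose and 0 fell over all genes, and 8 rose and 1 fell adjusted over the list alone, with Egr1 (1.34) and Ier3 (0.81). The median was 0.36 log2 with an adjusted p of 1.29e-05 by camera, and adjusted p = 0.433 with an estimated correlation. In the cytokine and chemokine list 2 of 27 rose and 0 fell over all genes, and 4 rose and 0 fell adjusted over the list alone, with Il18 (0.80) and Ccl8 (0.89). The median was 0.23 log2 with an adjusted p of 0.000475 by camera, and adjusted p = 0.519 with an estimated correlation. That median was 0.36 without KO descending replicate 2, and the call ended with the filter at the 50th percentile (adjusted p = 0.0545). In the interferon response 1 of 17 rose and 0 fell over all genes, and 3 rose and 0 fell adjusted over the list alone, with Irf7 (0.65). The median was 0.30 log2 with an adjusted p of 0.00037 by camera, and adjusted p = 0.519 with an estimated correlation. Its median was 0.61 without KO descending replicate 2, and its call ended without KO descending replicate 1 (adjusted p = 0.071, median 0.09). For macrophages and myeloid cells 2 of 25 rose and 0 fell over all genes, and 11 rose and 0 fell adjusted over the list alone, with the macrophage genes Adgre1 (0.89) and Cd68 (0.63). The median was 0.39 log2 with an adjusted p of 9.85e-07 by camera, and adjusted p = 0.305 with an estimated correlation. Beside them 0 of 18 neutrophil markers listed after seeing the data passed (median 0.42), and 0 of 9 platelet markers (median -0.06).

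Markers of liver and lung differed strongly between the descending pools. In the liver list 5 of 16 rose and 0 fell over all genes, and 13 rose and 0 fell adjusted over the list alone. The median was 1.45 log2 with an adjusted p of 7.63e-09 by camera, and adjusted p = 0.519 with an estimated correlation, and the median was 0.74 without KO descending replicate 2. Alb, albumin, read 9.05 and 10.20 on the KO descending arrays and 7.61 and 7.20 on the WT ones. For the epithelium of airway, oesophagus and lung 0 of 20 rose and 3 fell over all genes, and 0 rose and 9 fell adjusted over the list alone. The median was -0.41 log2 with an adjusted p of 0.000104 by camera, and adjusted p = 0.229 with an estimated correlation. That median was -0.22 without WT descending replicate 2, and the call ended with the filter at the 50th percentile (adjusted p = 0.167, median -0.17). Sftpc read 8.37 and 10.15 on the WT descending arrays and 4.74 and 5.07 on the KO ones.

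Further cell type lists differed in the descending aorta. Endothelial genes had Kdr lower (-0.54) and Flt1, another receptor of that growth factor family, higher (0.87), and 1 of 24 rose and 1 fell over all genes, and 2 rose and 10 fell adjusted over the list alone. The median was -0.25 log2 with an adjusted p of 0.00255 by camera, and adjusted p = 0.519 with an estimated correlation. For fat 1 of 22 rose and 1 fell over all genes, and 1 rose and 6 fell adjusted over the list alone, with Cidea, a lipid droplet protein, lower (-1.06) and Prdm16 higher (0.47). The median was -0.48 log2 with an adjusted p of 0.000195 by camera, and adjusted p = 0.519 with an estimated correlation. Without KO descending replicate 1 the fat median was -0.24. The mast cell list of 7 genes had a median of -0.48 log2 with an adjusted p of 0.00206 by camera, and adjusted p = 0.519 with an estimated correlation, with 0 called over all genes and 2 lower adjusted over the list alone.

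Striated muscle lists had no called member over all genes or adjusted over the list alone. Skeletal muscle genes had a median of 0.42 log2 with an adjusted p of 0.00531 by camera, and adjusted p = 0.753 with an estimated correlation, and 0.79 without KO descending replicate 2. Their call ended without WT descending replicate 1 (adjusted p = 0.116), without KO descending replicate 1 (0.711, median 0.22) and with the filter at the 50th percentile (0.167, median 0.80). Cardiomyocyte genes had a median of -0.33 log2 with an adjusted p of 0.0159 by camera, and adjusted p = 0.761 with an estimated correlation, and -0.51 without KO descending replicate 1. That call ended without WT descending replicate 2 (adjusted p = 0.505, median -0.20) and without KO descending replicate 2 (0.545, median -0.12).

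In the descending aorta limma called 380 genes between KO and WT, 243 higher and 137 lower, 300 of them by at least 1.5-fold. Arrays did not overlap in the 380 either, nor in 51.1% of tested genes (33.3% by chance). Of 75 named genes called, 8 kept the call under every alternative that tested them, namely Lox, Col8a1, Ccn5, Timp4, Col11a1, Adamts8, Itga11 and Itga4. The count was 20 and 48 without WT descending replicates 1 and 2, 73 and 63 without KO descending replicates 1 and 2, 226 without either WT ascending array and 204 without either KO ascending array. It was 105 when only the arrays compared entered the fit, 200 with the replicate number as a block, 48 in a test against 1.2-fold, 155 without the filter on dim genes, 717 with a filter at the 50th percentile, 919 with a trended robust prior and 31 when all probe sets were tested.

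**Figure D2:**
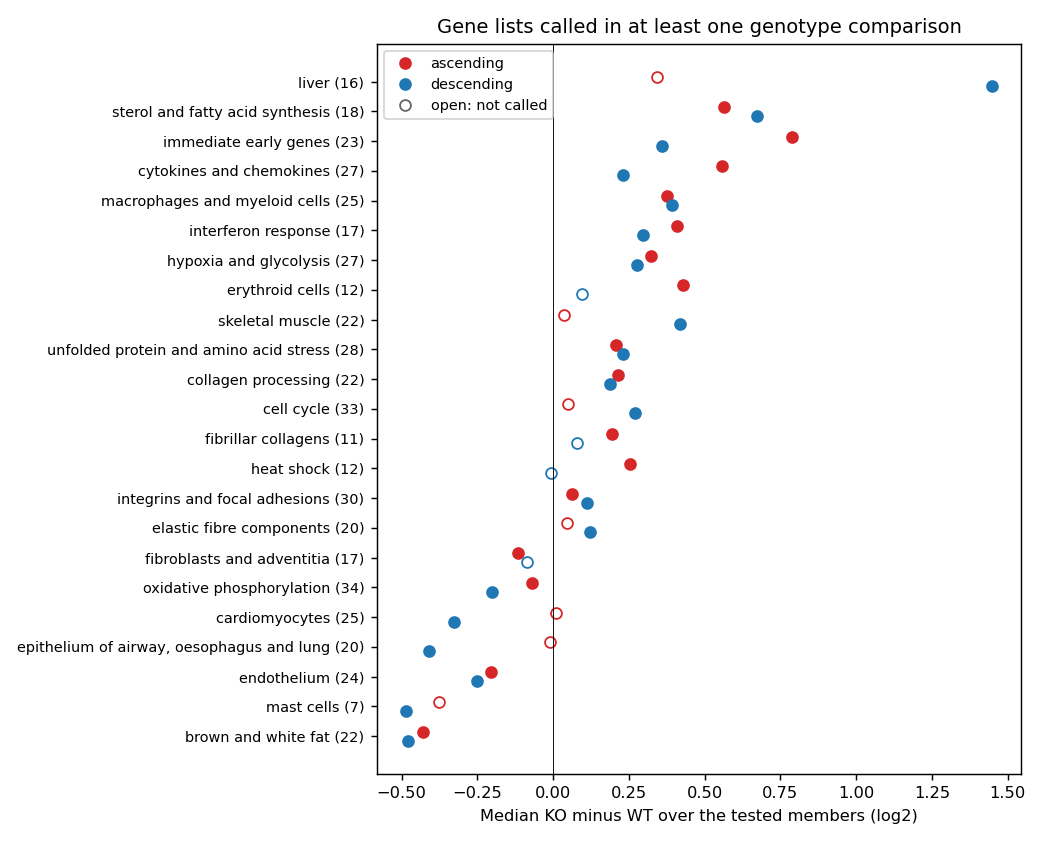
Median KO minus WT change in log2 units over the tested members (number in brackets) of each of the 23 gene lists called by camera in at least 1 segment, in red for ascending and blue for descending, with open circles where the call was not made. The descending liver median of 1.45 lies highest, and no list kept its call with an estimated correlation.

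The genotype effects of both segments largely pointed the same way. Limma called 164 genes in both segments, 103 higher and 61 lower in each, and 0 had opposite directions. Independent calls would share 3.75 and 1.63, but both tests used the same spread, and segments taken from the same pups were not excluded. Col8a1, Col11a1, Ccn5, P4ha1, Plod2, Adamts8, Itga11, Itga4 and Ptgs2 rose in both, as did Cyp51, Hmgcs1 and Insig1 of sterol synthesis, and Lox, Timp4, Ecm2, Mustn1 and Kdr fell in both. Of the genes called in ascending aorta 94.1% had the same sign in descending aorta, and 97.4% the other way round. Across all tested genes, which are not independent replicates, the changes had Pearson and Spearman correlations of 0.597 and 0.526.

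No gene passed in the test of the difference itself, the genotype by segment interaction in limma (0 of 16638, smallest adjusted p = 0.439), while 932 had an unadjusted p under 0.05. With a trended robust prior 1 gene passed, Abi3bp, and leaving out an array gave 0 to 11, with 2 genes without WT descending replicate 1 (Sftpc and Cxcl15), Sftpc alone without WT descending replicate 2, and 11 without KO descending replicate 1. For these genes and others chosen after their values were seen, the ascending minus descending difference of the genotype effect was 1.80 (adjusted p = 0.439) for Ptgs2, 3.40 (adjusted p = 0.439) for Csta3, 4.39 (adjusted p = 0.439) for Sftpc, 2.17 (adjusted p = 0.775) for Cxcl15 and -0.87 (adjusted p = 0.469) for Abi3bp. So no gene called in 1 segment is shown to differ between segments. Averaged over the segments, limma called 1902 genes between KO and WT, 1033 higher and 869 lower, 464 of them at 1.5-fold or more. The larger side depended on the processing, with 927 higher and 1059 lower when arrays were shifted to 1 median and 554 and 604 without WT descending replicate 2. The sterol and fatty acid synthesis list then had 13 of 18 members higher, 16 adjusted over the list alone, and a median of 0.66 log2 with an adjusted p of 1.72e-12 by camera, and adjusted p = 0.307 with an estimated correlation. The averaged count was 978 without WT ascending replicate 2, 782 and 1158 without WT descending replicates 1 and 2, 1063 and 1194 without KO ascending replicates 1 and 2, and 1005 and 1193 without KO descending replicates 1 and 2. It was 162 in a test against 1.2-fold and 691 when all probe sets were tested.

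**Figure D3:**
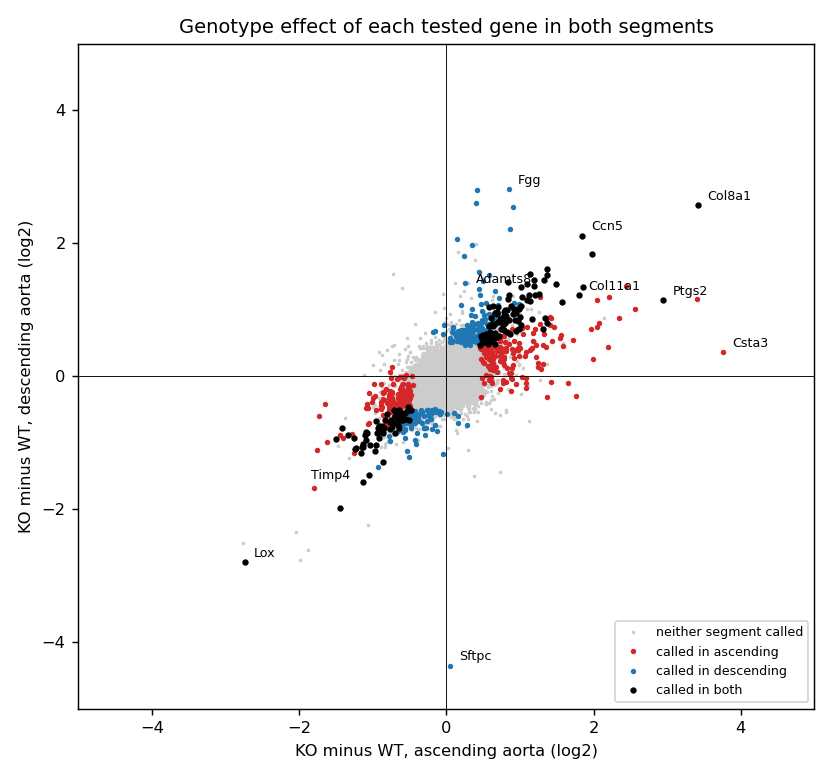
KO minus WT change in log2 units of each tested gene in the ascending (horizontal axis) and descending aorta (vertical axis), in red where called in ascending, blue in descending and black in both aortic segments. The 164 genes called in both lie at the lower left and the upper right, with Lox at -2.73 and -2.80 and Col8a1 at 3.41 and 2.57.

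The third comparison asked how the ascending and descending aorta differ in WT mice. Some Hox genes, which mark position along the body axis, were lower in the ascending aorta. Hoxb6 fell by 2.89 (SE 0.20, adjusted p = 0.000869) and Hoxc6 by 2.70 (SE 0.15, adjusted p = 0.000386) on the log2 scale. Tcf21, a transcription factor of mesenchymal cells, was higher by 2.04 (SE 0.11, adjusted p = 0.000386), Osr2, another transcription factor, by 2.34 (SE 0.23, adjusted p = 0.0034), and Efemp1, fibulin 3, by 1.60 (SE 0.14, adjusted p = 0.00248). The growth factor Ptn, pleiotrophin, was higher by 1.46, Kcnj15, a potassium channel, by 1.49, and Flrt3 by 1.69. Ahsg (2.05), Colec10 (1.79), Akr1c18 (1.46) and Sphkap (1.37) completed the largest rises. Falls included Sftpc (-4.60), Fads2b (-2.09) and the neuronal genes Tubb3 (-3.02), Ina (-2.80), Dbh (-2.79), Scg2 (-2.19) and Syt4 (-2.03).

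In the Hox list 0 of 27 tested members rose, 12 fell and 15 did not pass (1 rose and 14 fell when adjusted over the list alone), including Hoxa6 (-1.83) and Hoxb8 (-1.98), while Hoxb4 differed by -0.69 (adjusted p = 0.0695). The median was -0.48 log2 with an adjusted p of 2.18e-11 by camera, and adjusted p = 0.117 with an estimated correlation, and -0.24 without WT ascending replicate 1. For neurons, ganglia and Schwann cells 0 of 25 tested members rose, 8 fell and 17 did not pass (1 rose and 17 fell when adjusted over the list alone). Dbh and Ddc (-1.12), enzymes of catecholamine synthesis, and Stmn2 (-1.73), a protein of growing axons, were lower. The median was -0.91 log2 with an adjusted p of 1.01e-12 by camera, and adjusted p = 0.235 with an estimated correlation. Outflow tract and neural crest regulators had Dlx5 higher (1.32) and Prrx1 (-0.73) and Eya1 (-0.75) lower, and 1 of 32 rose and 2 fell over all genes, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0724). Among regulators of paraxial and trunk mesoderm Foxf2 (-1.16) and Meox2 (-0.76) were lower beside the higher Osr2 (camera adjusted p = 0.788). The fibroblast growth factor Fgf10 was higher (1.17) and Fgf7 lower (-1.01) in the ascending aorta.

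Matrix genes differed between the WT segments. Col8a1 (-1.74), Col12a1 (-0.76) and Col11a1 (-1.44) were lower in the ascending aorta. In the list of other collagens 0 of 21 rose and 2 fell over all genes, and 0 rose and 2 fell adjusted over the list alone. The median was -0.10 log2 with an adjusted p of 0.0188 by camera, and adjusted p = 0.333 with an estimated correlation. That call ended without WT ascending replicate 2 (adjusted p = 0.092) and without WT descending replicate 2 (0.196). Acan, aggrecan, was higher (0.79), Fmod lower (-0.83), Itgb8 (0.77) and Itga4 (0.69) higher and Itga11 lower (-0.89). Basement membrane genes included Col4a5 upwards (0.81) and Egfl6 downwards (-0.82), and 1 of 24 rose and 1 fell over all genes, and 5 rose and 1 fell adjusted over the list alone. The median was 0.10 log2 with an adjusted p of 0.0383 by camera, and adjusted p = 0.536 with an estimated correlation. This call ended without WT ascending replicate 1 (adjusted p = 0.149), without WT descending replicate 2 (0.179), with the replicate block (0.0573) and with the filter at the 50th percentile (0.133).

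In collagen processing Pcolce, an enhancer of procollagen cleavage, was lower (-0.57), and 0 of 22 rose and 1 fell over all genes, and 1 rose and 2 fell adjusted over the list alone. The median was -0.12 log2 with an adjusted p of 0.0441 by camera, and adjusted p = 0.536 with an estimated correlation. Its median was -0.18 without WT descending replicate 1. Its call ended without WT ascending replicate 2 (adjusted p = 0.286), without WT descending replicate 2 (0.217), without either KO descending array (0.0527), with the replicate block (0.0587) and with the mean of a gene's probe sets (0.0524). The TGF-beta list rose, and 1 of 34 rose and 0 fell over all genes, and 1 rose and 0 fell adjusted over the list alone, with Smad6, an inhibitor of the pathway (0.77). The median was 0.15 log2 with an adjusted p of 0.00015 by camera, and adjusted p = 0.429 with an estimated correlation. That median was 0.09 without WT descending replicate 2. Smooth muscle contractile genes had no called member over all genes, 2 higher adjusted over the list alone, and a median of 0.11 log2 with an adjusted p of 0.0428 by camera, and adjusted p = 0.536 with an estimated correlation. This call ended without WT ascending replicate 2 (adjusted p = 0.242, median 0.07), without WT descending replicate 1 (0.119), without either KO ascending array (0.0671), with the filter at the 50th percentile (0.063) and with only the arrays compared (0.0646).

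Several groups of markers were lower in the WT ascending aorta. For endothelium 0 of 24 tested members rose, 5 fell and 19 did not pass (0 rose and 9 fell when adjusted over the list alone), with Vwf, von Willebrand factor (-1.16), Plvap (-1.17) and Kdr (-0.79). The median was -0.28 log2 with an adjusted p of 1.97e-10 by camera, and adjusted p = 0.235 with an estimated correlation. In brown and white fat 0 of 22 rose and 3 fell over all genes, and 0 rose and 15 fell adjusted over the list alone, with Adipoq (-1.17), Lpl (-0.93) and Scd1 (-0.95). The median was -0.67 log2 with an adjusted p of 5.01e-11 by camera, and adjusted p = 0.384 with an estimated correlation. Oxidative phosphorylation, with 0 of 34 members called and 3 lower adjusted over the list alone, had a median of -0.22 log2 with an adjusted p of 1.02e-09 by camera, and adjusted p = 0.235 with an estimated correlation. Mast cell genes, with 0 called and 7 of 7 lower adjusted over the list alone, had a median of -0.82 log2 with an adjusted p of 1.60e-06 by camera, and adjusted p = 0.384 with an estimated correlation, and -0.53 without WT ascending replicate 1. For epithelium of airway, oesophagus and lung 0 of 20 rose and 2 fell over all genes, and 0 rose and 6 fell adjusted over the list alone, with Sftpc and Krt14 (-0.83). The median was -0.38 log2 with an adjusted p of 0.000372 by camera, and adjusted p = 0.235 with an estimated correlation. That median was -0.24 without WT ascending replicate 1 and -0.23 without WT descending replicate 2.

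Cardiomyocyte genes, with 0 called and 9 lower adjusted over the list alone, had a median of -0.73 log2 with an adjusted p of 0.000295 by camera, and adjusted p = 0.536 with an estimated correlation. That call ended without WT ascending replicate 1 (adjusted p = 0.0533, median -0.38) and without WT descending replicate 2 (adjusted p = 0.0593). The list of T and B cells and thymus was higher in the ascending aorta by its median of 0.37 log2 with an adjusted p of 0.0134 by camera, and adjusted p = 0.536 with an estimated correlation, although its called member, the B cell gene Cd79b, was lower (-0.85). Adjusted over the list alone 3 members were higher and 2 lower. The median was 0.03 (adjusted p = 0.856) without WT ascending replicate 1 and 0.71 without WT ascending replicate 2. Without WT descending replicate 2 the call ended as well (adjusted p = 0.0614).

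The cytokine, myeloid and interferon lists had negative medians in the WT ascending aorta. The cytokine and chemokine list had Cxcl13 (-1.59), a B cell attractant, and Ccl11 (-1.27) lower, and 0 of 27 rose and 2 fell over all genes, and 0 rose and 3 fell adjusted over the list alone. The median was -0.09 log2 with an adjusted p of 0.0188 by camera, and adjusted p = 0.536 with an estimated correlation. Without WT ascending replicate 1 the median was -0.22, and the call ended without WT ascending replicate 2 (adjusted p = 0.361) and without WT descending replicate 2 (0.0614). Macrophage and myeloid genes (median -0.19 log2 with an adjusted p of 0.00034 by camera, and adjusted p = 0.384 with an estimated correlation) and interferon response genes (median -0.17 log2 with an adjusted p of 0.00685 by camera, and adjusted p = 0.536 with an estimated correlation) had 0 members called, over all genes or adjusted over the list alone. Both calls ended without WT ascending replicate 2 (adjusted p = 0.161 and 0.111), and without WT ascending replicate 1 the myeloid median was -0.31. Sterol and fatty acid synthesis had Scd1 lower, 1 member over all genes and 1 adjusted over the list alone. The median was -0.17 log2 with an adjusted p of 0.00355 by camera, and adjusted p = 0.536 with an estimated correlation. That median was -0.27 without WT ascending replicate 1, and the call ended without WT ascending replicate 2 (adjusted p = 0.105) and without WT descending replicate 2 (0.0702).

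Between the WT segments limma called 247 genes, 85 higher and 162 lower in the ascending aorta, 233 of them by at least 1.5-fold. Arrays did not overlap in the 247 either, nor in 42.4% of tested genes (33.3% by chance). Of 56 named genes called, 12 kept the call under every alternative that tested them, namely Tcf21, Efemp1, Kcnj15, Ptn, Hoxb6, Hoxc6, Hoxa6, Col11a1, Cxcl13, Vwf, Ddc and Fgf10. The count was 65 without WT ascending replicate 1 and 84 and 63 without WT descending replicates 1 and 2. It was 72 in a test against 1.2-fold, 444 with a trended robust prior and 32 when all probe sets were tested.

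**Figure D4:**
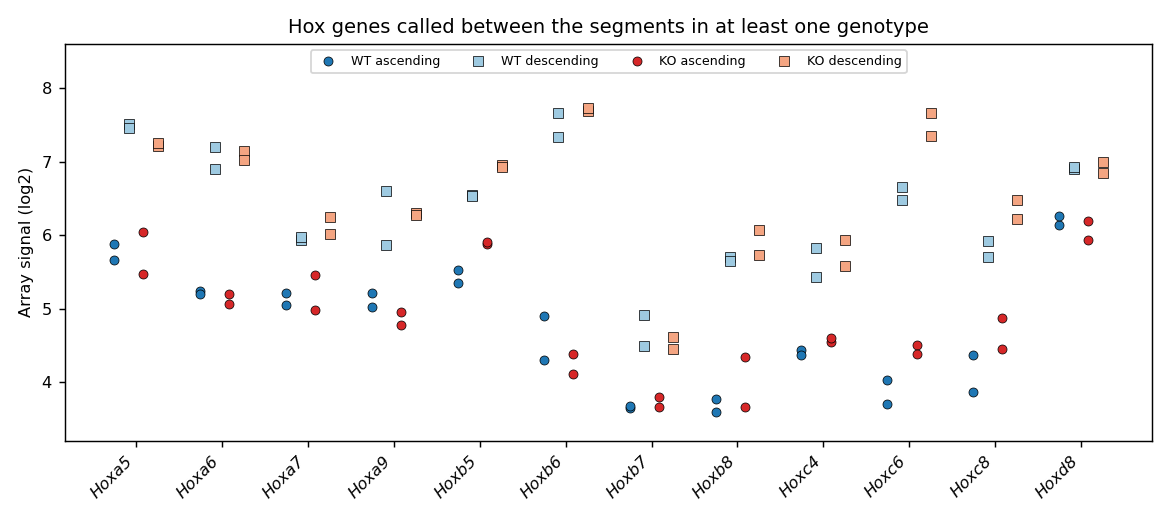
Array signal in log2 units of the 12 Hox genes called between the segments in at least 1 genotype, with circles for ascending and squares for descending arrays, in blue shades for WT and red shades for KO. Each gene is higher on every descending array than on every ascending array of the same genotype.

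The fourth comparison asked for the same contrast of segments in KO mice. In the ascending KO aorta, against the descending, Hoxb6 fell by 3.46 (SE 0.20, adjusted p = 0.00025) and Hoxc6 fell by 3.06 (SE 0.15, adjusted p = 9.01e-05) on the log2 scale. Tcf21 was higher by 2.69 (SE 0.11, adjusted p = 5.94e-05), Ptgs2 by 2.31 (SE 0.18, adjusted p = 0.00159) and Ptn by 2.22 (SE 0.11, adjusted p = 9.01e-05). Csta3 (2.46), Cst9 (2.09), Colec10 (1.85), Osr2 (1.81), Kcnj15 (1.58), Kcnip4 (1.53) and the platelet gene Ppbp (1.49) were also higher. The largest falls were in neuronal and neuroendocrine genes, Dbh (-2.80), Chgb (-2.60), Scg2 (-2.51), Tubb3 (-2.46), Ina (-2.41), Stmn2 (-2.02) and Gng3 (-1.98), and in C1qtnf3 (-2.04).

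The Hox list again had 12 of 27 members lower and 0 higher, with 14 lower and 2 higher adjusted over the list alone. The median was -0.43 log2 with an adjusted p of 7.22e-11 by camera, and adjusted p = 0.137 with an estimated correlation. For neurons, ganglia and Schwann cells 0 of 25 rose and 12 fell over all genes, and 1 rose and 14 fell adjusted over the list alone. The median was -0.89 log2 with an adjusted p of 3.37e-13 by camera, and adjusted p = 0.301 with an estimated correlation. In endothelium 0 of 24 rose and 5 fell over all genes, and 1 rose and 15 fell adjusted over the list alone, with Vwf (-0.97), Plvap (-0.94) and Kdr (-0.87). The median was -0.42 log2 with an adjusted p of 4.97e-14 by camera, and adjusted p = 0.293 with an estimated correlation. In brown and white fat 0 of 22 rose and 4 fell over all genes, and 0 rose and 14 fell adjusted over the list alone, with Car3 (-1.88) and Adipoq (-1.59). The median was -0.72 log2 with an adjusted p of 4.95e-12 by camera, and adjusted p = 0.462 with an estimated correlation. Outflow tract and neural crest regulators had Prrx1 (-0.67) and Eya1 (-0.82) lower while the list's median was above 0, at 0.16 log2 with an adjusted p of 0.0411 by camera, and adjusted p = 0.412 with an estimated correlation, and 0 of 32 rose and 2 fell over all genes, and 7 rose and 3 fell adjusted over the list alone. That call ended without KO ascending replicate 1 (adjusted p = 0.0959, median 0.10) or 2 (0.093) and without KO descending replicate 1 (0.131) or 2 (0.0716). It also ended without the filter (0.0523), with the filter at the 50th percentile (0.297, median 0.08) and with arrays shifted to 1 median (0.0675).

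Of the matrix genes Efemp1 (1.24), Pcolce2 (0.67), Acan (0.64), Itgb8 (0.82) and Timp4 (0.71) were higher in the ascending KO aorta. Col11a1 (-0.86), Col12a1 (-0.70), Fmod (-0.89), Prelp (-0.62), Egfl6 (-1.02), Sparcl1 (-1.15) and Itga11 (-1.04) were lower, and Col8a1 differed by -0.89 (adjusted p = 0.104). No matrix list passed by camera, and the smallest adjusted p among collagen processing, other collagens and proteoglycans was 0.245. The growth factor antagonist Frzb (0.81), Fgf10 (0.62) and Inhba (0.79) were higher and Fgf7 (-0.86) lower.

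Immediate early genes had a median of 0.39 log2 with an adjusted p of 7.17e-11 by camera, and adjusted p = 0.301 with an estimated correlation, with 0 of 23 members called over all genes and 5 higher adjusted over the list alone. Sterol and fatty acid synthesis had a median of -0.31 log2 with an adjusted p of 6.49e-08 by camera, and adjusted p = 0.474 with an estimated correlation, with Scd1 lower (-1.07) and 4 members lower adjusted over the list alone, and its median was -0.20 without KO ascending replicate 1. Cell cycle genes, none called over all genes or adjusted over the list alone (0 in each), had a median of -0.23 log2 with an adjusted p of 1.94e-06 by camera, and adjusted p = 0.77 with an estimated correlation. It was -0.12 without KO ascending replicate 1 and -0.12 without KO descending replicate 1. Liver genes, with 0 called over all genes and 5 lower adjusted over the list alone, had a median of -0.71 log2 with an adjusted p of 3.43e-05 by camera, and adjusted p = 0.77 with an estimated correlation. The liver call ended without KO descending replicate 2 (adjusted p = 0.297, median -0.17), and the median was -1.26 without KO descending replicate 1.

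Mast cell genes, 0 called over all genes and 4 lower adjusted over the list alone, had a median of -0.67 log2 with an adjusted p of 0.000289 by camera, and adjusted p = 0.686 with an estimated correlation, and -0.36 without KO ascending replicate 1. Oxidative phosphorylation, macrophage and myeloid, skeletal muscle and cardiomyocyte lists had 0 members called, over all genes or adjusted over the list alone. Oxidative phosphorylation had a median of -0.11 log2 with an adjusted p of 0.000993 by camera, and adjusted p = 0.628 with an estimated correlation. The myeloid median was -0.19 log2 with an adjusted p of 0.00467 by camera, and adjusted p = 0.628 with an estimated correlation. Skeletal muscle had -0.31 log2 with an adjusted p of 0.0103 by camera, and adjusted p = 0.77 with an estimated correlation, and cardiomyocytes had -0.39 log2 with an adjusted p of 0.0366 by camera, and adjusted p = 0.77 with an estimated correlation. The myeloid call ended without KO ascending replicate 2 (adjusted p = 0.131, median -0.05). The skeletal muscle call ended without KO ascending replicate 1 (0.26, median -0.19) and without KO descending replicate 1 (0.841, median -0.05), and its median was -0.67 without KO ascending replicate 2 and -0.69 without KO descending replicate 2. The cardiomyocyte call ended without KO ascending replicate 1 (0.642, median -0.14), without KO descending replicate 1 (0.73, median -0.14) and without the filter (0.0523).

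Between the KO segments limma called 247 genes, 91 higher and 156 lower in the ascending aorta, 234 of them by at least 1.5-fold. Arrays did not overlap in the 247 either, nor in 41.0% of tested genes (33.3% by chance). Of 53 named genes called, 13 kept the call under every alternative that tested them, namely Tcf21, Ptgs2, Ptn, Colec10, Kcnj15, Hoxb6, Hoxc6, Hoxa6, Scg2, C1qtnf3, Stmn2, Cxcl13 and Ddc. The count was 61 and 108 without KO ascending replicates 1 and 2 and 148 and 54 without KO descending replicates 1 and 2. It was 114 when only the arrays compared entered the fit, 74 in a test against 1.2-fold, 430 with a trended robust prior and 35 when all probe sets were tested.

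The segment contrasts of both genotypes shared 138 called genes, 40 higher and 98 lower in ascending aorta in each, and 0 had opposite directions. Independent calls would share 0.465 and 1.52. Tcf21, Osr2, Efemp1, Ptn, Kcnj15 and Fgf10 were higher in the ascending aorta of both genotypes, and Hoxb6, Hoxc6, Hoxa6, Col11a1, Dbh, Stmn2, Vwf and Kdr were lower in both. Of the genes called in WT 98.0% had the same sign in KO, and 94.7% the other way round, and across genes the Pearson correlation of the changes was 0.518 and the Spearman correlation 0.305. Averaged over the genotypes, limma called 677 genes between the segments, 250 higher and 427 lower in the ascending aorta, 360 of them by at least 1.5-fold. The Hox list then had 13 of 27 members lower and 1 higher, 15 and 2 adjusted over the list alone, and a median of -0.48 log2 with an adjusted p of 1.41e-11 by camera, and adjusted p = 0.119 with an estimated correlation. The averaged count was 432 without WT ascending replicate 1, 390 and 437 without WT descending replicates 1 and 2, 427 without KO ascending replicate 1 and 429 without KO descending replicate 2. It was 176 in a test against 1.2-fold and 349 when all probe sets were tested.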

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

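The tests of the liver, lung, neutrophil, handling and normalization explanations below were chosen after the results were seen; the interaction with its alternatives and the splits of the arrays were planned.

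Camera called 11 gene lists in the interaction of genotype and segment, in which no single gene passed. The difference, ascending minus descending, had a median of -1.05 log2 for liver genes, -0.21 for cell cycle, -0.13 for sterol and fatty acid synthesis, 0.40 for epithelium of airway, oesophagus and lung and 0.37 for erythroid cells. It was 0.30 for immediate early genes, 0.30 for cytokines and chemokines, 0.20 for cartilage, 0.19 for heat shock, 0.14 for interferon response and 0.10 for oxidative phosphorylation. Adjusted p ranged from 2.97e-07 for liver to 0.0489 for the sterol list. With an estimated correlation no list passed (smallest adjusted p = 0.412), and fry called 0. Liver, cell cycle, immediate early and epithelium kept their calls whichever array was left out. Heat shock lost its call without WT ascending replicate 1 (adjusted p = 0.0721), WT descending replicate 1 (0.122, median 0.10) or KO descending replicate 2 (0.051), interferon without WT ascending replicate 2 (0.125), KO ascending replicate 1 (0.0924, median 0.04) or KO descending replicate 2 (0.724, median -0.03), and cytokines without WT ascending replicate 2 (0.125) or KO descending replicate 2 (0.051). Erythroid cells lost it without WT ascending replicate 2 (0.0528), WT descending replicate 2 (0.112) or KO descending replicate 1 (0.372, median 0.13). Cartilage lost it without WT ascending replicate 1 (0.319, median 0.10), WT descending replicate 1 (0.186), KO ascending replicate 1 (0.134) or KO descending replicate 1 (0.199), and oxidative phosphorylation without WT ascending replicate 1 (0.0771), WT descending replicate 1 (0.127, median 0.07), KO ascending replicate 2 (0.0869) or KO descending replicate 2 (0.051). The sterol list lost it without WT ascending replicate 1 (0.259), WT descending replicate 1 (0.289), KO ascending replicate 1 (0.962, median -0.03) or KO descending replicate 2 (0.193). With all arrays kept, cartilage and the sterol list also lost their calls with the replicate number as a block (0.0505 and 0.0562) and with cyclic loess (0.0633 and 0.113), and the sterol list with a filter at the 50th percentile (0.0831). The liver median was -1.72 without KO descending replicate 1 and -0.57 without replicate 2. Medians of other lists moved by more than 1.5 times while their calls held. Without WT ascending replicate 1 they were -0.09 for cell cycle, 0.27 for epithelium and 0.09 for interferon, and without WT descending replicate 1 interferon had 0.07. The sterol median was -0.22 without WT ascending replicate 2, -0.28 without KO ascending replicate 2 and -0.23 without KO descending replicate 1. Cell cycle had -0.13 without KO ascending replicate 1 and erythroid cells 0.20 without replicate 2. Immediate early genes had 0.18 without KO descending replicate 1 and 0.50 without replicate 2, and interferon had 0.31 without replicate 1.

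Among 12093 probe sets without a single gene name, which the comparisons of genes did not use, limma called 8 between KO and WT in the ascending aorta and 9 in the descending aorta, all higher in KO, of which the same 4 had equal values on every array, so 1 signal. It called 1 between the segments in WT and 1 in KO, both lower in the ascending aorta. At an unadjusted p under 0.05 the counts were 1203, 965, 821 and 663. The probe set called between the segments, chosen after its values were seen as were the others named here, is shared by Hoxa7 and Mira and was lower in the ascending aorta (-4.52 log2 in WT and -4.44 in KO). A pair of probe sets without a name in the platform table had larger changes between KO and WT than any gene tested. They were higher by 5.99 and 6.27 in the ascending and 5.56 and 6.22 in the descending aorta, and what they measure is not given in the sources used here. These equal 4, shared by the U3 small nucleolar RNA genes Rnu3b1 to Rnu3b4, were higher by 1.85 and 1.89.

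Liver and lung genes differed between pools. Of 16 liver genes 13 were higher on both KO than both WT descending arrays (16.7% by chance), which restates the rise. Of the 16, 15 were higher on KO descending replicate 2 than 1, so varied liver tissue may explain them. KO ascending arrays too had higher liver means (6.26 and 6.16 log2) than WT (5.92 and 5.85). All 10 lung secretory and surfactant genes were lower on both KO than both WT descending arrays, which restates the fall. Listed after the values were seen, all are in fixed lists too. Of these, 6 were higher on WT descending replicate 2 than 1, so they did not vary together. Lung tissue in the WT pools as their source stays open. A change in the aorta itself was tested for neither set and stays open.

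Of 50 immediate early and cytokine genes 18 rose in ascending KO aorta beside neutrophil markers. If neutrophil RNA were the source, the excess of these genes in descending over ascending KO pools should follow that of neutrophil genes. Of the 24 called higher averaged over the segments 16.7% lay above the upper quartile of neutrophil genes, as did 11 of all 50 tested members of both lists and, in a first choice, 2 of 18 called in the ascending aorta, so neutrophil RNA may contribute, but any cause stronger in the ascending aorta would give such shares too. The time between dissection and lysis is a candidate explanation as well. The immediate early list differed by at most 0.191 log2 between arrays of a group, against 0.723 between KO and WT ascending, while Fos, named after its values were seen, read 5.54 and 6.99 on the KO descending and 5.97 and 6.79 on the KO ascending arrays, and handling times are not given in the sources used here, so handling time and genotype cannot be told apart on these arrays.

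Sterol synthesis genes rose in KO in both segments (9 of 18). Liver tissue in the KO pools would give them the segment ratio of liver genes, but 100% of the 13 called higher averaged over the segments, 17 of all 18 tested members and, in a first choice, 9 of 9 called in both segments had an excess ratio of ascending over descending above the upper quartile of liver genes. A shift of all genes of like level through the normalization is argued against too, since the highest median of 10000 lists of the same size and level was 0.241 log2, against 0.657 for the sterol list averaged over the segments. A response of aortic cells to Lox loss, or a difference in the cell mixture, stays open and was not tested.

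The count of splits cannot exclude chance for the averaged comparisons, since every other split mixes real groups and carries their difference in its spread. Of the 34 splits of the 8 arrays that could be fitted with the segment as a term, 1, the real one, called as many genes as the 2004 of the genotype split, and the highest other called 0. With the genotype as a term, 1 of 34 called as many as the 688 of the segment split, and the highest other again called 0. Both real counts come from a fit with 1 term per factor.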

How the results depend on the processing

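Lox kept its direction and its call under every alternative, at -2.67 to -2.80 log2 in the ascending and -2.71 to -2.88 in the descending aorta when 1 array was left out. Of 78 list calls, the interaction included, 66 were kept under every alternative that kept all arrays and the preset correlation, 48 whichever array was left out, and 0 with an estimated correlation. Of 261 calls of named genes, beside both of Lox, 42 were kept under every alternative other than leaving out an array and 59 whichever array was left out, and none of the 261 turned direction. Of the 1902 genes called in the averaged genotypes 2 did with the mean of a gene's probe sets. No called list turned the direction of camera, but the medians of integrins and focal adhesions in the descending aorta (-0.01 without KO descending replicate 1) and of interferon response in the interaction (-0.03 without KO descending replicate 2) changed sign as the calls were lost.

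The counts of called genes moved more. Without the filter 303 genes were called between KO and WT in the ascending and 155 in the descending aorta, and with a filter at the 50th percentile 756 and 717. A trended robust prior, whose prior df was 8.03 against 4.51, gave 1014, 919, 444 for the segments in WT, 430 in KO and 1 for the interaction. All probe sets tested separately, 31009 in number, gave 39, 31, 32 and 35 for the 4 comparisons, 691 for the averaged genotypes and 349 for the averaged segments. A test against 1.2-fold gave 65, 48, 72, 74, 162 and 176 in that order, as it asks for more than a difference from 0. A minimum of 1.5-fold left 464 and 360 in the averaged comparisons. With only the arrays compared in the fit, which leaves fewer residual df, 100 genes were called in ascending and 105 in descending aorta and 114 between the KO segments. With the replicate number as a block 200 were called in the descending aorta. A stricter null and fewer arrays act by their construction. Testing all probe sets changed both the number tested and the prior df (2.55), which were not separated, and for the filters, the prior and the block the cause was not tested.

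With 1 array left out, the counts ranged from 64 to 353 for KO against WT in the ascending and 20 to 226 in the descending aorta, 63 to 224 between the WT and 54 to 191 between the KO segments. They ranged from 0 to 11 for the interaction, 782 to 1317 for the averaged genotypes and 390 to 542 for the averaged segments. An alternative chosen after seeing the data left out WT ascending replicate 1, with the most thymus signal, and KO descending replicate 2, with the most liver signal. It gave 90, 37, 33 and 45 genes in the 4 comparisons, 0 in the interaction and 743 and 221 in the averaged ones. Skeletal muscle genes between the WT segments (median 0.01, not called, with a camera direction opposite to that of the median) had a median of 0.12 and an adjusted p of 0.0499 without WT ascending replicate 1, and -0.38 without replicate 2, with an adjusted p of 0.0151. Changes of scaling by cyclic loess or by shifting arrays to 1 median kept all 7 counts within 1.5 times. In the averaged genotypes the larger side turned with arrays shifted to 1 median and without WT descending replicate 2. Signal near background limits what can be said of dim genes, and those below 4.11 log2 were left out by the filter.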

Other observations

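Growth factors of the developing vessel changed singly without Lox. In the ascending aorta Angpt1, a ligand of the endothelial receptor Tie2, fell by 0.87 log2 (adjusted p = 0.0151) and Fgf10 by 0.76 (adjusted p = 0.0151), and Fgf7 rose by 0.58 (adjusted p = 0.0385). In the descending aorta Pdgfc fell by 0.74 (adjusted p = 0.029) and Fgf18 rose by 0.75 (adjusted p = 0.0305). As a list, 1 of 42 rose and 3 fell over all genes, and 4 rose and 6 fell adjusted over the list alone in the ascending aorta (camera adjusted p = 0.455), and 1 of 42 rose and 1 fell over all genes, and 2 rose and 2 fell adjusted over the list alone in the descending aorta (camera adjusted p = 0.504). Among regulators of development, Dlx5 fell by 0.76 (adjusted p = 0.0287) and Foxc2 rose by 0.71 (adjusted p = 0.0466) in the ascending aorta. Hoxc6 rose by 0.94 (adjusted p = 0.0274) and Hoxb9 by 0.57 (adjusted p = 0.0472) in the descending aorta, where 2 of 27 Hox genes passed over all genes, 3 rose and 1 fell adjusted over the list alone, and the list had a median of 0.03 (camera adjusted p = 0.686).

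Vasoactive genes in the ascending aorta included Edn1, endothelin 1, which rose by 0.62 (adjusted p = 0.0224), and Ptgs2. In the descending aorta Gucy1a1, a subunit of the nitric oxide receptor, fell by 0.54 (adjusted p = 0.0472). The list had medians of 0.07 and -0.11 (camera adjusted p = 0.817 and 0.336). Among p53 targets Plk2 rose by 0.53 (adjusted p = 0.0477) and Eda2r fell by 0.60 (adjusted p = 0.0497) in the ascending aorta, and the list's median of 0.07 and mean of -0.12 had opposite signs (camera adjusted p = 0.605). Chromosomal neighbours of Lox did not shift as a list (median -0.03, camera adjusted p = 0.455 in ascending; -0.03 and 0.821 in descending aorta), and Lmnb1, a nuclear lamin, rose by 0.54 (adjusted p = 0.0472) in the descending aorta. Cytosolic ribosomal proteins had medians of -0.02 and -0.02, with 0 of 27 called in either segment.

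Some arrays carried marker signals that their partners did not. Genes of T and B cells and thymus had a mean of 5.77 log2 on WT ascending replicate 1 and 4.89 on replicate 2. Scgb1a1, an airway gene named after its values were seen, read 8.25 on WT ascending replicate 2 and 4.66 on replicate 1.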
